A study of Mus musculus with 7 samples.

How the data were processed

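Total RNA of mouse lung, extracted with Trizol and sequenced after a standard Illumina library preparation per the labels, was measured in 7 libraries of the C57BL/6 strain. The labels put 4 libraries in the wild type group and 3 in the knockout group, in which the secretoglobin gene Scgb3a2 is targeted. The libraries are named here by genotype and by the number in their titles (WT2, WT3, WT4, WT6, KO3, KO4 and KO5). A letter P, which all 7 titles carry before the number, is left out of these names and was not interpreted. The labels give no sex, age, litter, collection time or sequencing batch, and do not say whether each library came from its own mouse, so that p-values measure the spread between these libraries.

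The deposited values are whole-number read counts per gene, not normalized, with a different total in each library. The submitters' processing notes name STAR, DESeq2 and the genome build mm10, without versions or roles. The program that counted the reads, its gene annotation and its strand setting are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies, such as immunoglobulin variable segments and protocadherin beta genes, could therefore have been split or shared, and values of such genes are uncertain. The count table names genes by symbol only. Of its 28828 entries, 562 had a total of 0, 31 shared a symbol with another entry and were kept apart, and 24 carried symbols that had been turned into calendar dates. Positions came from the GENCODE M21 annotation of GRCm38 (the assembly also called mm10), matched by symbol for 28636 entries (99.3%).

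Totals ranged from 13071262 to 16480006 counts per library. In the shallowest library, KO5, the 3 counts taken as the limit that a count of 0 allows correspond to 0.23 CPM (counts scaled to the library total). Without molecular identifiers, counting intervals (95%, exact Poisson or binomial) and these limits cover counting error only. The pair of libraries with the smallest difference in counts still had a chi-square of 4.67 per degree of freedom, well above sampling noise, so that each library was counted once.

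Genes were compared between genotypes with edgeR 4.0.16 in R 4.3.3, using its filter on low counts with the genotype groups (19832 genes kept), TMM normalization and the robust quasi-likelihood test with genotype as the only term. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold of a call. CPM values use the TMM-scaled library sizes, and log2 CPM for list scores and principal components uses a prior count of 2. Before the data were examined, 37 gene lists were fixed for lung cell types, immune cells, pathways and neighbouring tissues. Of these, 35 with at least 5 measured genes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. The mast cell, basophil and eosinophil list had too few measured genes, and the sex-linked list served as a check of the samples. Each list was also tested with camera at an estimated correlation and with fry. The number of list genes past the threshold when adjusted over the list alone is given beside the count over all genes. Enrichment of called genes near Scgb3a2 was tested with Fisher's exact test, two-sided, in a window of 20 Mb.

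The genes named in the text were chosen by a rule fixed before the data were examined. It takes Scgb3a2, then up to 12 called genes per direction with the largest fold change, whose knockout values all lie on 1 side of the wild type values, with a mean of at least 1 CPM and a symbol that is not a predicted gene, then the 5 called genes with the smallest p not yet named. It then takes up to 4 genes with the smallest p from each list, called or not. Since fewer than 12 genes passed in each direction, genes with the smallest p were added until 10 were reached, and these are said not to pass. Gm94 came in through the smallest p. Genes named outside this rule (Jchain, Pigr, Dmbt1, Tff2, Chia1, Ighv9-3, Pcdhb8, Bpifa1, Dbp and the other clock genes called in a split of the libraries) were chosen after their values were seen. Scgb1a1 and Rn7sk, given as shares of library counts, also stand outside this rule.

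The procedure was tested on simulated counts of 19832 genes in 4 against 3 libraries, drawn 6 times with 200 changed genes. With dispersions following the trend over expression, 3.16% of the calls were false on average. With dispersions as uneven between genes as estimated here, the average was 7.77% (range over draws 3.33% to 11.1%), above the nominal 5%, so that calls close to the threshold carry more doubt than their adjusted p states. In the same uneven draws, 76.8% of genes changed 2-fold and 98.5% of genes changed 4-fold were recovered. The adjusted threshold is stricter where fewer genes change. With 7 calls in the real comparison against 200 changed genes in the draws, these shares are likely too high for the real comparison. Changed genes were drawn only among those with a mean above 2 CPM, and these draws held no shared difference of WT6 and KO5. A missing call therefore does not exclude a 4-fold change where libraries of a group vary widely, as with the immunoglobulin genes below.

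Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling and library totals alone in place of TMM, other filters on low counts, DESeq2 1.42.0, limma-voom with and without quality weights, the title number as a block, 1 surrogate variable from sva 3.50.0, leaving out each library in turn, other thresholds, and leaving out sex-linked, immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes. A term for WT6 and KO5 against the other 5 libraries, the 5 libraries alone, and some tests of the chromosomal window were added after seeing the data. Fold changes of genes at 0 in a whole group depend on edgeR's prior count, so for these a bound against 3 counts over the group is given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.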

Results

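RNA sequencing of whole lung compared C57BL/6 mice carrying a knockout of Scgb3a2 with wild type mice. Scgb3a2 encodes a small secreted protein of the secretoglobin family, made mainly by airway secretory (club) cells. The design asks which transcripts of the lung differ when this gene is disrupted. There were 4 wild type and 3 knockout libraries with totals of 13071262 to 16480006 counts, and 25868 to 26885 genes had at least 1 count in a library.

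Scgb3a2 itself (chromosome 18, 43764289 to 43767399, plus strand, GRCm38) fell from 252 ± 41.3 CPM in wild type lung (SD, n = 4) to 1.72 ± 0.83 CPM in knockout lung (SD, n = 3). The counts were 4204, 4170, 2636 and 4165 in the wild type libraries and 19, 19 and 37 in the knockout libraries. This left 0.51%, 0.48% and 1.06% of the wild type mean in KO3, KO4 and KO5. The log2 fold change was -7.20 ± 0.27 (SE) with an adjusted p of 8.06e-07 in edgeR's quasi-likelihood test. An exact two-sided permutation test of log2 CPM gave p = 0.0286, the smallest that the 35 splits of 4 and 3 libraries allow. Every library therefore carried the Scgb3a2 level its label states. The part of the gene that the allele removes is not given in the sources used here, so the origin of the remaining reads is open.

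Apart from Scgb3a2, few genes passed the test over the whole transcriptome. Spink5, which encodes the serine protease inhibitor LEKTI of squamous epithelia, fell from 7.25 ± 1.54 CPM to 0.07 ± 0.13 CPM (adjusted p = 0.000843). Gm94, a predicted protein-coding gene, had counts of 0 in all 4 wild type libraries and of 23, 30 and 50 in the knockout libraries (adjusted p = 0.0246). Greb1l, a homologue of the oestrogen-regulated gene Greb1, rose from 10.7 ± 1.05 to 26.9 ± 7.67 CPM (log2 fold change 1.32 ± 0.19 SE, adjusted p = 0.0404). The other 3 genes that rose were variable segments of the immunoglobulin heavy chain, Ighv5-16 (log2 fold change 4.32, adjusted p = 0.00245), Ighv1-80 (3.03) and Ighv1-22 (2.76), the latter both with an adjusted p of 0.0172. In all, edgeR called 7 of 19832 genes, 5 higher and 2 lower in knockout lung, and all 7 had knockout values that did not overlap the wild type values. An unadjusted p under 0.05 was found for 569 genes (2.87%), and 418 genes lay higher and 320 lower in all knockout libraries than in all wild type libraries, 3.72% of those tested against 5.71% by chance.

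The number of calls depended on single libraries and on the test. It was 3 without WT2, 3 without WT3 and 3 without WT4, where Gm94, Greb1l, Ighv1-22 and Ighv1-80 lost their calls. It was 41 without KO3, where 21 of the 34 added genes were immunoglobulin genes, and 60 with DESeq2 (53 higher, 7 lower). Gm94 also lost its call without KO4, and Greb1l without KO4 or without KO5. Scaling by library totals alone gave 5 calls (3 higher, 2 lower), without Gm94 and Greb1l. Genes with the next smallest p that did not pass were Igkv3-2, an immunoglobulin light chain segment (5.16, adjusted p = 0.0524), the protocadherin Pcdhb9 (-1.16, 0.0629), the calcium-dependent kinase Camk4 (1.35, 0.126) and the chemokine Ccl20 (3.33, 0.151), each given as log2 fold change and edgeR's adjusted p.

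**Figure D1:**
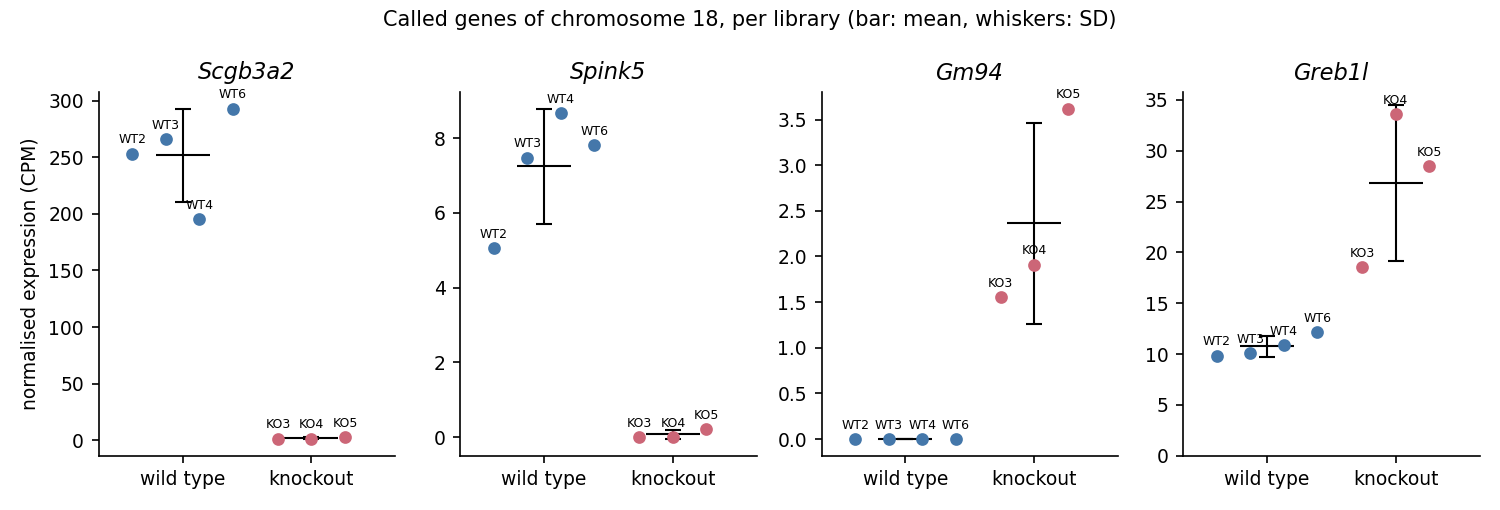
Expression per library (y axis, CPM on a linear scale) of Scgb3a2, Spink5, Gm94 and Greb1l in wild type (blue) and knockout (red) lung, with horizontal bars for means and whiskers for SD (n = 4 and n = 3). Scgb3a2 and Spink5 lie near 0 in the 3 knockout libraries, Gm94 lies at 0 in the 4 wild type libraries, and Greb1l ranges from 9.82 to 12.2 CPM in wild type and from 18.5 to 33.6 CPM in knockout libraries.

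The next comparison asked whether called genes lie close to the targeted gene, since DNA around a targeted allele can differ from that of the wild type strain. Gm94 (chromosome 18, 43777196 to 43792878, minus strand) lies 9.80 kb beyond the 3' end of Scgb3a2 on the opposite strand, and Spink5 (43963235 to 44022501, plus strand) lies 196 kb beyond it. Spink5 counts summed to 429 in wild type and 3 in knockout libraries. With the TMM-scaled library sizes this was a 106-fold difference, with a 95% counting interval of 35.9 to 514. Gm94 was 46.5-fold higher in knockout lung when set against 3 counts over the wild type group, and the lower 95% counting bound of its ratio was 37.1. Leaving out Scgb3a2, 2 of 278 tested genes within 20 Mb were called against 4 of 19411 elsewhere, with an odds ratio of 35.1 (95% interval 3.16 to 245, p = 0.00287, Fisher's exact test, two-sided). Over the whole chromosome, which adds Greb1l at 10.3 Mb, 3 of 464 genes were called (odds ratio 41.7, exact p = 0.000247). Neighbouring genes are not independent, and the calls of Gm94 and Greb1l depend on single libraries as given above. Of genes on this chromosome that did not pass, Camk4 (1.35, adjusted p = 0.126) lies 10.6 Mb from Scgb3a2, within the window. Pcdhb8 (log2 fold change 1.24, adjusted p = 0.164) and Pcdhb9 belong to 1 cluster of similar copies, also within the window. Their values went in opposite directions.

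**Figure D2:**
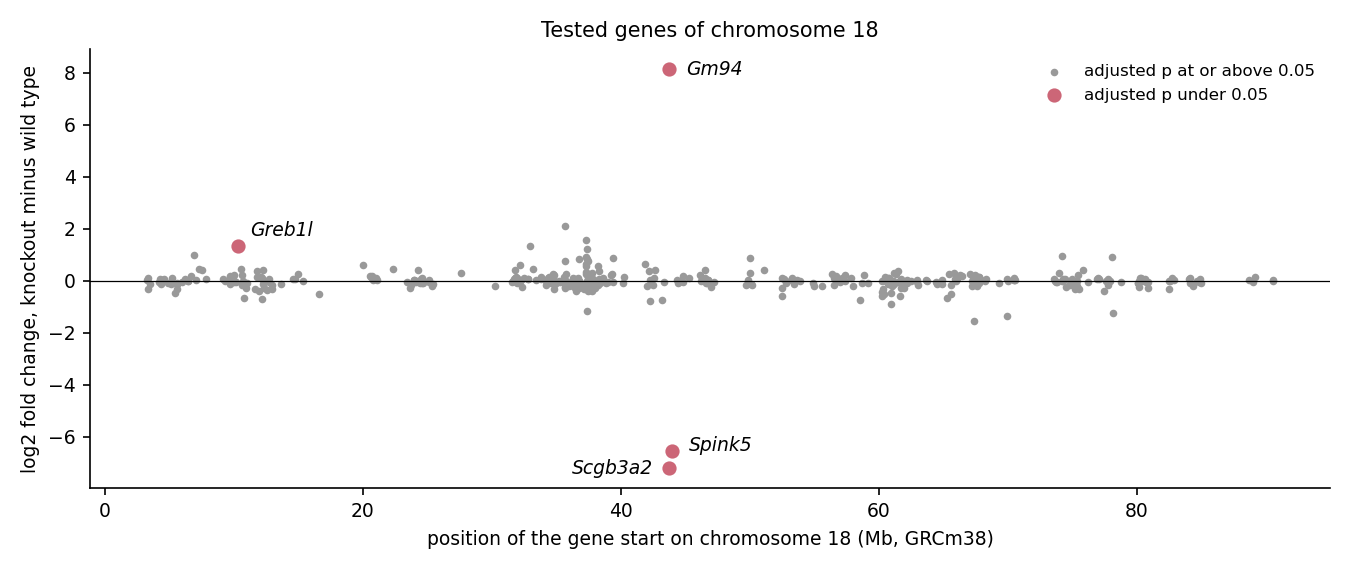
Log2 fold change, knockout minus wild type (y axis), of each tested gene against its start on chromosome 18 (x axis, Mb, GRCm38), with genes at an adjusted p under 0.05 in red and the rest in grey. Gm94 (8.14), Spink5 (-6.57) and Scgb3a2 (-7.20) lie at nearly the same position and Greb1l (1.32) lies at 10.3 Mb, while the fitted value of Gm94 depends on edgeR's prior count because its wild type counts are 0.

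The libraries also differed in a way that the genotypes do not explain. The leading principal component of log2 CPM (37.5% of the variance) set WT6 (36.3) and KO5 (49.98) apart from the other 5 libraries (-30.5 to -5.59). The next component (19.6%) ordered the genotypes, with wild type libraries between 3.09 and 26.7 and knockout libraries between -33.0 and -13.4. WT6 and KO5 also had the highest scores of the mesothelium list, 4.69 and 4.51 mean log2 CPM against 3.14 to 3.74 in the others. They had the lowest shares of Scgb1a1, the main club cell secretoglobin, 0.876% and 0.715% of counts against 1.24% to 1.41%. Scgb1a1 did not stand for its cell type here, since the club and secretory cell list score was highest in this pair (7.47 and 7.43 against 7.06 to 7.32). With a term for WT6 and KO5 in the fit, an alternative chosen after seeing the data, 29 genes were called (22 higher, 7 lower), including all 7 above. Among the 5 libraries without WT6 and KO5, 14 genes were called (10 higher, 4 lower), 6 of them shared with the 7, and Greb1l lost its call (adjusted p = 0.0696, with a range over all its alternatives of 1.27e-11 to 0.324).

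**Figure D3:**
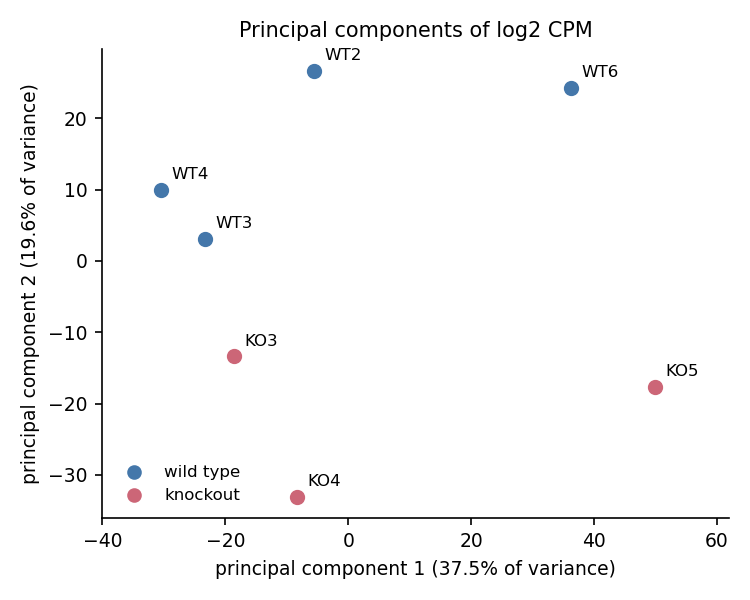
Principal components of log2 CPM over the tested genes, with each point a library, wild type in blue and knockout in red, and axes in arbitrary units of component score. WT6 and KO5 lie to the right of the other 5 libraries along component 1 (37.5% of the variance), and the genotypes lie on opposite sides of 0 along component 2 (19.6%).

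Transcripts of antibody-secreting and B cells formed the gene group with the largest difference between genotypes. Igha, the constant region of immunoglobulin A, had 40.5 ± 2.23 CPM in wild type (n = 4) and 436 ± 405 CPM in knockout lung (n = 3), with 122, 293 and 894 CPM in KO3, KO4 and KO5. Igkc, the kappa light chain constant region, had 37.2 ± 7.18 and 380 ± 224 CPM, with 133, 438 and 570 CPM in the knockout libraries. The joining chain Jchain had 8.73 ± 2.69 and 138 ± 154 CPM, and the heavy chains Ighg2c and Ighg2b had log2 fold changes of 6.10 ± 1.24 and 5.40 ± 1.21 (SE). The plasma cell list was called higher, with a median log2 fold change of 2.59 over 11 measured genes (camera adjusted p = 3.15e-38). No gene of it passed over all genes in edgeR, where Igkc had an adjusted p of 0.406 and Igha of 0.965, and 9 rose when adjusted over the list alone. The call was lost at an adjusted p of 0.0945 with an estimated correlation. The list score was higher in each knockout library (3.87, 5.02 and 6.27) than in any wild type library (2.28 to 3.07). An exact two-sided permutation test of this score gave p = 0.0286, the smallest possible, and an adjusted p of 0.5 over the lists. The median was 1.69 without KO5 and 1.59 without both WT6 and KO5.

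The B cell list was called higher as well, with a median of 1.37 over 16 genes, all of them with a positive value (camera adjusted p = 9.19e-24, and adjusted p = 0.248 with an estimated correlation). Its genes included the surface receptors Cd22 (8.60 ± 2.37 CPM in wild type and 23.1 ± 14.5 CPM in knockout lung) and Cd79a (3.59 ± 1.27 and 11.1 ± 7.85 CPM). No gene of it passed over all genes or when adjusted over the list alone. Its score overlapped between genotypes, since KO3 (2.14) lay below WT2 (2.51) and WT6 (2.80), and KO5 had the highest score (4.44), without which the median was 0.61. The T and NK cell list had a median of 0.39 (camera adjusted p = 8.85e-07, and adjusted p = 0.460 with an estimated correlation). Only Cd4, the co-receptor of helper T cells, passed when adjusted over the list alone, with 3.82 ± 0.43 and 9.13 ± 3.26 CPM. The thymus and lymphocyte precursor list, which shares Cd8b1 with the T and NK cell list, had a median of 0.40 (camera adjusted p = 0.00739, and adjusted p = 0.460 with an estimated correlation), with Satb1 at 20.1 ± 4.60 and 30.8 ± 11.98 CPM. Without KO5 both lists lost their calls (medians 0.16 and 0.21), and the thymus list also lost its call without WT4 (0.21).

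**Figure D4:**
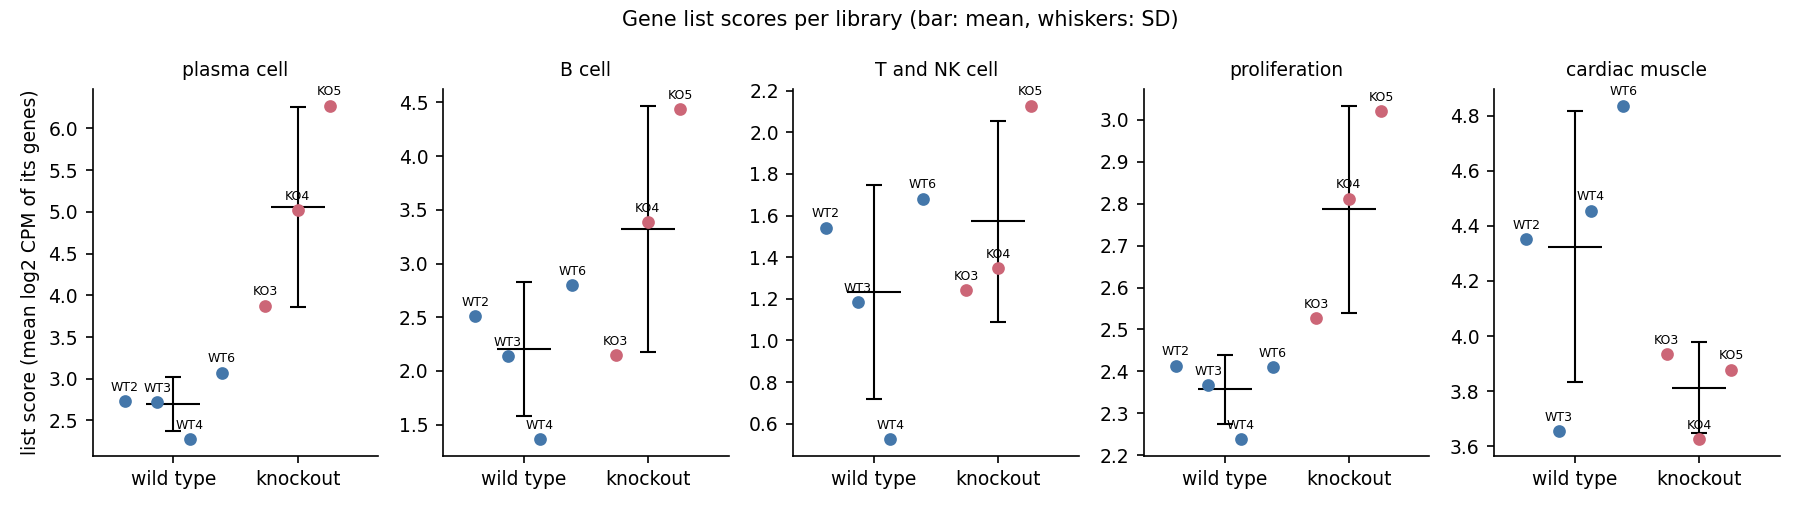
List scores per library (y axis, mean log2 CPM of the genes of a list, each panel with its own range) for wild type (blue) and knockout (red) lung, with horizontal bars for means and whiskers for SD (n = 4 and n = 3). Plasma cell and proliferation scores do not overlap between genotypes, while B cell, T and NK cell and cardiac muscle scores do.

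Genes of cell division formed the other large group on the higher side. All 23 genes of the proliferation list had positive values, with a median log2 fold change of 0.46 (camera adjusted p = 5.75e-20, and adjusted p = 0.248 with an estimated correlation). The proliferation marker Mki67 had 40.7 ± 5.54 CPM in wild type and 72.0 ± 18.04 CPM in knockout lung, and Nusap1 and Cenpf of the mitotic spindle and centromere had log2 fold changes of 0.62 ± 0.17 and 0.49 ± 0.15 (SE). No gene of the list passed over all genes, and 3 rose when adjusted over the list alone. The list score was 2.24 to 2.41 in wild type libraries and 2.53, 2.81 and 3.02 in KO3, KO4 and KO5, the same order of knockout libraries as in the plasma cell score. Its exact permutation p was also 0.0286, with an adjusted p of 0.5 over the lists.

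Lists of inflammatory genes were called higher too. The inflammatory cytokine and NF-kB target list had a median of 0.20 over 14 genes (camera adjusted p = 5.97e-06, and adjusted p = 0.248 with an estimated correlation), and Ccl20, a chemokine for lymphocytes and dendritic cells, was the 1 gene that rose when adjusted over the list alone (0.22 ± 0.02 and 2.26 ± 1.70 CPM). The neutrophil list had a median of 0.25 over 12 genes (adjusted p = 0.00334, and 0.274 as the adjusted p with an estimated correlation). Its leading gene was Lcn2, with 115 ± 56.2 and 250 ± 74.7 CPM, which airway epithelium also makes. The type 2 airway inflammation list was called higher (adjusted p = 0.0352, and adjusted p = 0.460 with an estimated correlation) although its median was 0.01 and its mean 0.62. That mean rested on the goblet cell products Clca1 and Muc5ac. Clca1 had 1.02 to 4.71 CPM in wild type libraries and 3.11, 108 and 117 CPM in KO3, KO4 and KO5, and Muc5ac had 2.81 to 4.37 CPM and 4.66, 17.8 and 79.1 CPM. The IL-33 receptor Il1rl1 of the same list had 6.34 ± 0.95 and 4.77 ± 0.24 CPM. None of these lists had a gene past the threshold over all genes, and neither the neutrophil nor the type 2 list had one when adjusted over the list alone. The type 2 list lost its call without WT2, WT3, WT4, KO4 or KO5 (medians -0.05 to 0.02) and with the added term for WT6 and KO5 (-0.05) or among the 5 libraries without this pair (-0.03). With each library left out in turn, the neutrophil median ranged from 0.11 (without KO4) to 0.37 (without WT6) and the cytokine median from 0.16 (without WT6) to 0.37 (without WT4), and both calls held.

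Muscle and adipose genes lay lower in knockout lung. The cardiac muscle list, which marks heart muscle of the pulmonary veins or of adjoining heart, had a median of -0.58 over 19 genes (camera adjusted p = 5.18e-16, and adjusted p = 0.272 with an estimated correlation). The atrial light chain Myl4 had 37.3 ± 14.8 and 20.7 ± 5.20 CPM, the heavy chain Myh6 350 ± 117 and 220 ± 24.0 CPM, and Tnni3 32.0 ± 8.31 and 19.9 ± 6.15 CPM. The score of WT3 (3.66) lay within the knockout scores (3.63 to 3.94). The skeletal muscle list, which shares Ckm with the cardiac list, had a median of -0.15 (adjusted p = 0.0311, and adjusted p = 0.460 with an estimated correlation), with the oxygen carrier Mb of heart and skeletal muscle at 23.5 ± 9.02 and 11.8 ± 2.62 CPM. The adipose list had a median of -0.59 (adjusted p = 0.000285, and adjusted p = 0.460 with an estimated correlation), where the lipid droplet protein Plin1 had 14.1 CPM in WT6 and 1.40 to 3.07 CPM in the other wild type libraries. Among the 5 libraries without WT6 and KO5 the medians were -0.38, -0.0045 and -0.27 for cardiac muscle, skeletal muscle and adipose, and the skeletal muscle call was lost. It was also lost without WT2, WT6, KO4 or KO5 (medians -0.18 to -0.09) and kept without WT3, WT4 or KO3 (-0.27, -0.25 and -0.32), and the adipose call was lost without WT6 (-0.016). No gene of these lists passed over all genes or when adjusted over the list alone.

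The other lists called lower had medians close to 0. They were smooth muscle (-0.16), interferon response (-0.17), endothelium (-0.13), ciliated cell (-0.08) and extracellular matrix and fibroblast (-0.08), with camera adjusted p of 0.00739, 0.000399, 0.0129, 0.0129 and 0.0138. With an estimated correlation the smooth muscle list had an adjusted p of 0.248 and the other lists of this group an adjusted p of 0.460. Examples with log2 fold changes were the myosin kinase Mylk (-0.28), the endothelial receptor Kdr (-0.26), the axonemal protein Hydin (-0.18) and the fibroblast enzyme Inmt (-0.50). In the interferon list, Rtp4 (-0.44) and Gbp3 (-0.48) had values opposite to the chemokine Cxcl9 (1.36). Calls were lost without KO5 for smooth muscle (median -0.12), without WT2, WT4 or KO5 for endothelium (-0.08, -0.10 and -0.05), without WT2 or KO4 for ciliated cells (-0.06 and -0.08), and without WT4 or KO5 for extracellular matrix (-0.06 and -0.07). With each library left out in turn, medians ranged from -0.24 to -0.12 for smooth muscle and from -0.16 to -0.05 for endothelium. They ranged from -0.14 to -0.06 for ciliated cells and from -0.13 to -0.06 for extracellular matrix. The interferon call held, at -0.24 to -0.11. Among the 5 libraries without WT6 and KO5, the endothelium (-0.09, adjusted p = 0.0879) and extracellular matrix (-0.06, adjusted p = 0.257) calls were lost too. No gene of these lists passed over all genes or when adjusted over the list alone.

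The list of the airway cell type that makes Scgb3a2 did not pass. This club and secretory cell list had a median of -0.05 over 19 genes (camera adjusted p = 0.381), ranging from -0.12 without KO4 to 0.08 without KO5, with Scgb3a1, a related secretoglobin, at 108 ± 15.3 and 164 ± 72.7 CPM, haptoglobin (Hp) at 415 ± 50.7 and 342 ± 38.2 CPM, and the antimicrobial lectin Reg3g at 22.4 ± 14.9 and 125 ± 154 CPM. With the added term for WT6 and KO5 this list was called lower (median -0.06, adjusted p = 0.00222, with a range over all its alternatives of 0.00222 to 0.911, and adjusted p = 0.199 with an estimated correlation). It then had 1 gene higher and 3 lower when adjusted over the list alone. Among the 5 libraries without WT6 and KO5 it was called lower at a median of -0.02 (adjusted p = 0.0118, and adjusted p = 0.489 with an estimated correlation). In both fits the airway secretory protein Bpifa1 was the only gene of this list past the threshold over all genes. Its log2 fold change was -2.66 with the term and -2.49 among the 5 libraries, while 8 of the 19 genes had positive values in each fit. The list was not tested without Bpifa1. The alveolar type 2 cell and surfactant list (median -0.05, adjusted p = 0.238) and the alveolar type 1 cell list (-0.06, 0.322) did not pass. The chemokine Cxcl15 of type 2 cells had 557 ± 111 and 418 ± 32.6 CPM. The alveolar macrophage list (0.08, 0.238), with the scavenger receptor Marco at 9.61 ± 2.22 and 12.4 ± 3.73 CPM, and the inflammasome and pyroptosis list (0.06, 0.452), with Casp4 at 13.3 ± 1.93 and 15.1 ± 2.71 CPM, did not pass either. The NRF2 and xenobiotic metabolism list (-0.03, 0.486) held 1 gene higher and 1 lower when adjusted over the list alone, the carboxylesterase Ces1g (6.98 ± 1.05 and 12.3 ± 2.70 CPM) and the cytochrome Cyp2a5 (96.0 ± 26.3 and 52.2 ± 5.18 CPM). Single libraries mattered here too. The type 2 cell list was called lower without KO4 (median -0.10), although its median was 0.08 without KO5, the type 1 cell list was called lower without WT6, KO3 or KO4 (-0.14, -0.18 and -0.13) and higher without KO5 (0.07), and the NRF2 list was called lower without WT2 (-0.06), while the alveolar macrophage list was called higher without WT3 or KO5 (0.11 and 0.17) and among the 5 libraries without WT6 and KO5 (0.15, adjusted p = 0.00364, and adjusted p = 0.542 with an estimated correlation), although its median was -0.02 without KO4.

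Across the 35 lists, 16 were called by camera at the preset correlation, 8 higher and 8 lower, and 0 at an estimated correlation, where 6 had an unadjusted p under 0.05. With fry, 0 lists passed, and 2 had an unadjusted p under 0.05. In the exact permutation test of list scores the lowest adjusted p was 0.5, for the plasma cell and proliferation lists. Of the 643 genes of these lists, 0 were called by edgeR and 0 by limma-voom, 72 had an unadjusted p under 0.05 in edgeR, and 10 were called by DESeq2. The Y-linked gene Eif2s3y had 47.1 ± 13.7 CPM in wild type and 61.3 ± 2.51 CPM in knockout lung. Xist, which female cells express, had 6.65 ± 0.90 and 11.0 ± 0.63 CPM (edgeR adjusted p = 0.503). Over single libraries, Eif2s3y ranged from 30.5 to 63.6 CPM and Xist from 5.62 to 11.7 CPM. Every library therefore held male tissue, and the source of the Xist reads was not tested.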

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

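The window around Scgb3a2 was fixed before the data were examined, and the splits, the set of WT6 and KO5 and all other tests of explanations in this part were chosen only after the results were seen. Of 106 measures compared among the 4 wild type libraries, 6 had 1 library far from the other 3, where chance gives about 5% of such groups. In WT6 these were Bpifa1, an airway secretory protein, at 595 CPM against 82.2 to 103 in the other wild type libraries, Cyp2a5 at 135 CPM against 79.6 to 85.7, Plin1 at 14.1 CPM against 1.40 to 3.07, and the nuclear RNA Rn7sk at 0.815% of counts against 1.15% to 1.20%. In WT3, Tnni3 had 19.5 CPM against 35.9 to 36.6. In WT4, Rtp4 had 13.03 CPM against 14.6 to 14.9.

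Called genes were concentrated around Scgb3a2, and both calls within 20 Mb, of Spink5 and Gm94, also held among the 5 libraries without WT6 and KO5 (2 of 3 genes, the exception being Greb1l), which argues against that library difference as their source. For Gm94, the lower 95% counting bound of the knockout to wild type ratio, 37.1, only restates its rise, and a strain variant that raises its expression stays open. For Spink5 the ratio was 0.00947, and without the reads a loss of mapping through strain variants cannot be told apart from a loss of expression. A candidate explanation is DNA of the embryonic stem cell strain around the targeted allele, or a local effect of the allele on its neighbours, and the odds ratio of 35.1 for calls within 20 Mb fits that hypothesis without separating its forms. Gm94 lies between Scgb3a2 and Spink5 and had 23, 30 and 50 counts in the knockout libraries, which a single deletion running from Scgb3a2 into Spink5 would not leave.

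The plasma cell list score was higher in each of the 3 knockout libraries than in any wild type library. The exact permutation p of 0.0286 for this score became 0.5 when adjusted over the lists. The values without WT6 and KO5 argue against this pair as the whole source of the higher score, though part of its size went with the pair. Among the other 5 libraries the plasma cell median was 1.59 against 2.59 in all libraries, with KO3 and KO4 both above WT2, WT3 and WT4 in list score. In those 5 libraries the list had a camera adjusted p of 0.186 with an estimated correlation, and no gene of it passed over all genes. Lymph node or other lymphoid tissue in the sampled lung remains open, because the T and NK cell score was only 0.34 higher (mean log2 CPM, knockout minus wild type) with overlapping values, while the B cell score was highest in KO4 and KO5. In KO3 the T and NK cell score (1.24) and the B cell score (2.14) lay near the wild type means (1.23 and 2.20), although its plasma cell score (3.87) lay above all wild type values. An effect of the genotype on antibody-secreting cells in the lung is a hypothesis that these data leave open, as are age, housing and litter, which the labels do not give.

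The third pattern is the distance of WT6 and KO5 from the other 5 libraries, where 2781 genes (1243 higher, 1538 lower) passed in a test of a split taken from the data, so that this number describes the pattern and is no independent evidence of it. WT6 and KO5 had the lowest totals, but 2773 genes passed after all libraries were thinned to 1 total, which argues against depth. After trends with GC content and exon length were removed, 3308 genes passed against 2762 in the same genes before, which argues against those trends as the whole cause. Another composition of the sampled tissue stays open, since WT6 and KO5 had the highest mesothelium scores (4.69 and 4.51 against 3.14 to 3.74), and the ribosomal protein genes (25 of 76 higher, 18 lower) do not decide it without a profile of the other tissue. The pair also had the lowest shares of the nuclear RNA Rn7sk, 0.815% and 0.848% of counts against 1.15% to 1.35% in the others. The labels give no sequencing batch, and a technical difference stays open as well. The labels give no group that matches this pair, and no biological explanation was tested.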

How the results depend on the processing

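The term for WT6 and KO5, the fits without this pair, the threshold of 0.001 in the chromosomal window and the comparison with other splits were chosen after seeing the data. Scgb3a2 kept its direction and its call in every alternative run (log2 fold change -7.65 to -7.00 when each library was left out in turn), as did Spink5. Ighv5-16 kept its call in the 19 alternatives in which it was tested, with a highest adjusted p of 0.0331 over them. The number of called genes, 7 in the main analysis, was 5 to 10 under other scalings, filters and thresholds and with limma-voom. It was 60 with DESeq2, 36 with 1 surrogate variable, 29 with the term for WT6 and KO5, 14 among the other 5 libraries, and 3 to 41 when each library was left out in turn. It was 3 without sex-linked, immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes, since the immunoglobulin segments were then not tested and Greb1l no longer passed. The DESeq2 calls held all 7 genes and 30 immunoglobulin genes, and the cause of the larger number was not tested. With the title number as a replicate block, 140 genes were called (106 higher, 34 lower) on 1 residual degree of freedom. The numbers 3 and 4 occur in both genotypes. The deviations of WT3 and KO3 (r = 0.236) and of WT4 and KO4 (0.201) correlated about as much as the crossed pairs. These were WT3 with KO4 (0.221) and WT4 with KO3 (0.236). So few pairs cannot decide whether a shared number marks a litter or a day, which the labels leave open. The 16 list calls became 0 with camera at an estimated correlation and 0 with fry, and were 12 to 19 when each library was left out in turn. Some lists that the main analysis did not call were called in other fits. Among the 5 libraries, the immediate early and heat shock list was lower (-0.20, adjusted p = 2.77e-05, and 0.542 as the adjusted p with an estimated correlation). With libraries left out in turn its median ranged from -0.20 to 0.08, called lower without WT3, WT6 or KO5. Mitochondrial transcripts were higher among the 5 libraries (0.22, adjusted p = 0.000483, and 0.521 as the adjusted p with an estimated correlation) and with the term for WT6 and KO5 (0.11, 0.0380 and 0.695). Their median ranged from -0.11 to 0.36 with libraries left out, called higher without WT3 or KO5. With that term the mesothelium list was lower (-0.14, adjusted p = 0.0380, and 0.516 with an estimated correlation), and its median ranged from -0.60 (without KO5, called) to 0.32 (without WT6). Ribosomal proteins were higher with the term (0.05, adjusted p = 0.0274, and 0.811 with an estimated correlation), and from -0.0011 to 0.07 with libraries left out, called without WT3 or KO4. The unfolded protein response list was lower among the 5 libraries (-0.10, adjusted p = 0.0416, and 0.520 with an estimated correlation), and from -0.07 to 0.02 with libraries left out, without a call. The alveolar type 1 cell list (median -0.06, not called) was called lower without KO3 (-0.18) and higher without KO5 (0.072), so its direction rests on single libraries. Of 35 list medians, 3 changed sign under upper quartile scaling and 3 under library totals alone, none of them past the threshold, and the median of all genes lay between -0.0068 and 0.0082. The odds ratio in the chromosomal window stayed past the threshold at 5 Mb (272), over the whole chromosome (41.7), at an unadjusted p under 0.001 (17.1) and with the term for WT6 and KO5 (15.4). A count of 0 bounds expression only to 0.23 CPM in KO5.

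Other splits of the 7 libraries into 4 and 3 were fitted in the same way. Of the 35 splits, 2 called as many genes as the genotypes did (7), the real one and that of WT2, WT6 and KO5 against the rest, which called 1199, so chance cannot be excluded by this count, and a number this far above the real one points to a structure of the samples. With the term for WT6 and KO5, again 2 of the 35 splits called as many genes as the genotypes (29), with 534 the highest of the others. For the lists, 7 of the 35 splits called as many as the genotypes (16), with 20 the highest of the others.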

Other observations

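Apart from DESeq2 and the surrogate variable, the tests in this part, and the choice of the genes in it, were made only after the results were seen. With the term for WT6 and KO5 in edgeR's fit, 22 genes passed that were not among the 7 main calls. They included immunoglobulin genes, the T cell co-receptor Cd4 (1.18) and Camk4 (1.33), which lies on chromosome 18 at 10.6 Mb from Scgb3a2. Pcdhb9 (-1.17) and Pcdhb8 (1.25) of the same chromosome passed as well, with uncertain values as similar copies. In this fit, 5 of 278 genes within 20 Mb of Scgb3a2 were called against 23 of 19411 elsewhere. The genes described next share no fixed list and were not tested as a group, and the club and secretory cell list was called lower in this fit (median -0.06, adjusted p = 0.00222, and adjusted p = 0.199 with an estimated correlation), whereas most of them rose. Bpifa1, which is among them, belongs to that list and was its only gene past the threshold over all genes. Pigr, the receptor that carries immunoglobulin A across epithelium, was higher (log2 fold change 1.18 ± 0.11 SE, adjusted p = 0.000211), with 36.0 to 51.9 CPM in wild type and 69.9, 91.1 and 146 CPM in knockout libraries. The mucosal scavenger protein Dmbt1 (4.17 ± 0.44), the trefoil factor Tff2 (1.36 ± 0.17) and the chitinase Chia1 (0.58 ± 0.10) were higher too. Bpifa1 (-2.66 ± 0.17) and Cyp2a5 (-0.88 ± 0.11) were lower, with Bpifa1 at 19.9, 12.9 and 75.0 CPM in KO3, KO4 and KO5 against 82.2 to 595 CPM in wild type libraries. None of these 6 genes passed in edgeR with genotype as the only term, where the lowest adjusted p was 0.347 (Chia1). With DESeq2, fixed before the data were examined, Pigr, Tff2, Chia1 and Cyp2a5 passed, and with 1 surrogate variable, also fixed before, all but Bpifa1 did. The surrogate variable was 0.55 in WT6 and 0.62 in KO5 against -0.33 to -0.06 in the other libraries. It therefore largely repeats the term for this pair and is no independent test of these genes. Among the 5 libraries without WT6 and KO5, Pigr, Bpifa1 and Cyp2a5 passed and Dmbt1, Tff2 and Chia1 did not. Of the 29 calls, 8 were immunoglobulin genes, among them Ighv9-3 (2.67).

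Several clock genes differed between libraries by a split other than that of the genotypes or of WT6 and KO5. Nr1d1, a repressor in the circadian loop, had 128, 109 and 59.7 CPM in WT2, WT6 and KO5 against 40.9, 38.5, 21.5 and 23.0 CPM in WT3, WT4, KO3 and KO4, and its target Arntl had 4.88, 5.06 and 8.98 CPM against 7.98, 10.5, 12.8 and 17.6 CPM, with KO5 above WT3. The split of WT2, WT6 and KO5 from the other 4 libraries is also the one with 1199 called genes. In that split, 6 of 18 clock genes passed (33.3%) against 1193 of 19814 other genes (6.02%), an odds ratio of 7.80 (95% interval 2.40 to 22.5, Fisher's exact test, two-sided). The genes were Ciart (0.98), Per3 (0.45), Hlf (0.61), Bhlhe41 (0.52) and Dbp (1.91), higher in the 3 libraries, and Clock (-0.44), lower. Arntl (-0.96) lay opposite to Nr1d1 (1.68), both without passing. Not all clock genes went with this split, since Npas2 (-0.40, unadjusted p = 0.277 in the split) lay higher in every knockout library (2.32 to 3.63 CPM) than in any wild type library (1.085 to 1.998 CPM). Between genotypes, Npas2 (0.92, unadjusted p = 0.00740) and Arntl (0.89, unadjusted p = 0.0125) were higher in knockout lung, with an adjusted p near 1 for both. A hypothesis that these values fit is that the 3 lungs were collected at another time of day than the other 4, which the labels do not record. The clock pattern was noticed in the same libraries in which it was tested, so this may be read as a lead for checking collection records and not as a finding.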
